A study of Homo sapiens with 32 samples.

How the data were processed

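RNA-seq libraries of primary breast tumours and of liver and lung metastases were prepared from frozen tissue with a poly(A)-selecting kit, per the labels' protocols. The genome build was hg38, per the submitters' processing notes. The aligner, the counting program, its version and its strand setting are not given in the sources used here. The authors deposited raw counts per gene for 32 libraries and 62703 genes, in a table whose columns resemble featureCounts output, per the file headers. The library titles gave the donor as a shared prefix, the site and a replicate number, and the series design calls the metastases matched, so the donor was taken as a true pairing of sites. The labels give the tissue both as obtained at autopsy and as collected at surgery, and neither was used. Donors are called A to G.

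The authors also deposited 3 tables of differential expression, for breast, liver and lung, per the file headers with the columns of a limma output table. The deposited logFC, AveExpr and t columns were read as scores on an unknown scale, because AveExpr lay between 0.206 and 1.9 for every gene. The deposited p-value column used was the adjusted one, and the authors' adjustment method is not given in the sources used here. A further deposited table joined the tumour counts with 42 columns of normal tissue that do not belong to this series, and these columns were not used. From it came only a column of gene names, which per the file headers came from the table of normal tissue, and the number of normal columns per organ, 14. The mean of the normal tissue on the deposited scale was computed from the authors' AveExpr, logFC and the numbers of libraries (6, 14 or 12 tumour and 14 normal), and called 0 within a tolerance of 1e-06.

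Totals per library lay between 18854457 and 29614222 counts. Mitochondrial genes held a median of 6.12% of counts in breast (range 3.48 to 10.4), 5.45% in liver (1.25 to 14.5) and 7.96% in lung (2.73 to 12.7). Libraries of the same donor and site were compared in 17 pairs by the chi-square per degree of freedom of their counts, which lay between 8.01 and 143.4. Counts were therefore summed per donor and site into 16 sums, and the donor was the replicate. Intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules. In the tables, 1722 genes shared a name with another ID and were kept apart by ID.

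Differential expression was tested in R 4.3.3 with edgeR 4.0.16, by a quasi-likelihood F test with TMM factors, filterByExpr by site (30328 genes) and the model of donor plus site with all 3 sites in 1 fit, which left 7 residual degrees of freedom. Adjusted p are Benjamini-Hochberg values over all genes of a comparison, with a threshold of 0.05. Log2 CPM used a prior count of 2. Standard errors are those of the fitted log2 fold change. A gene with 0 counts in a group of the paired donors was given a lower bound of its fold against a floor of 3 counts over the group, and a gene with 1 to 3 counts a ratio with a 95% counting interval.

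Gene lists, 27 in number, were tested with camera (limma 3.58.1) with a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over the lists of a comparison. Members were also counted when adjusted over the list alone. *FABP4* and *PPARG* stood in both the adipocyte and the macrophage list. The lists covered programmes studied in breast tumours (ER and luminal identity, oestrogen response, HER2 amplicon, basal and myoepithelial, proliferation, mesenchymal transition), other cell types (hepatocyte, liver transcription factor, lung epithelium, adipocyte, skin and keratinocyte, fibroblast and matrix, endothelium, muscle, T and NK cell, B and plasma cell, macrophage and Kupffer, neutrophil, red blood cell) and states (antigen presentation, interferon response, immediate early and AP-1, hypoxia, heat shock and unfolded protein, oxidative phosphorylation, lipid and cholesterol metabolism, mitochondrially encoded). The lists, tests, alternatives and the rule for named genes were chosen before the data were examined. The rule named, per comparison and direction, the 8 genes of largest fold that passed, had a mean log2 CPM of at least 1 and moved the same way in every pair. Pairs tied at 0 counts in both sites could pass as moving, which let in *CFHR2*, *SERPINA7* and *CIMIP1*. The rule then named the 2 members of smallest adjusted p per list. The rule also named up to 6 genes per direction of each deposited table, and always *ESR1*, *PGR*, *ERBB2*, *FOXA1*, *GATA3*, *MKI67*, *KRT19*, *ALB* and *SFTPC*. Sex-linked marker genes, variable immune receptor segments and unnamed or clone IDs were left out. A minimum mean level planned for the deposited tables could not be applied on their narrow scale. Other list members given as examples were chosen after their values were seen.

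Overlap and correlation between the sites were set beside 12 simulated sets in which no gene changed and the breast sums were shared. Similarity was the median Pearson correlation of log2 CPM of pairs of sums, tested with 1e+05 permutations of donors within sites. Alternatives were DESeq2 size factors, DESeq2's Wald test (1.42.0), limma-voom with the donor as a random effect, no filter, no donor block, single libraries, the first library only, the compared sites only, donors with all 3 sites, each donor left out, and TMM factors without cell type genes. Fits without the breast library of donor E or the liver libraries of donor A were added after seeing the data. The edgeR procedure was tested on simulated data with 200 of 30328 genes changed by known folds. It recovered 29%, 17% and 60% of 4-fold and 84%, 81% and 92% of 16-fold changes in liver against breast, lung against breast and liver against lung, with 5 of 118, 8 of 106 and 4 of 156 calls false. The changed genes were drawn only from those with a mean log2 CPM of at least 1, with the fitted spread. These shares therefore do not give the power for other genes of the data. In lung against breast, 0 of 19 lung epithelium genes passed over all genes, at a median of 4.20. Figures were drawn with python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.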

Results

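Gene expression was measured by RNA-seq of polyadenylated RNA in frozen tissue of breast cancer described as oestrogen receptor-positive. The tissue came from the primary breast tumour and from liver and lung metastases of the same donors. The deposited table of gene counts held 32 libraries from 7 donors, here called A to G. There were 6 libraries of primary breast tumour (donors E, F and G), 14 of liver metastasis (all 7 donors) and 12 of lung metastasis (all donors but E). Library totals ran from 22117604 to 29614222 counts in breast, from 19902776 to 28676589 in liver and from 18854457 to 25756815 in lung. Counts were summed per donor and site, which gave 16 sums, and sites were compared within donors. Liver and breast were paired in 3 donors, lung and breast in 2, and liver and lung in 6. All 3 sites were in 1 fit. A fitted fold therefore also draws on donors that lack that pair, and it can differ from the pairs themselves. Donor E had 1 breast library, and only donors F and G had all 3 sites.

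By median correlation, tumours from different organs of the same donor resembled each other more than tumours from the same organ of different donors. Over 30328 genes, the median Pearson correlation of log2 CPM, counts scaled to library size, was 0.913 for 11 pairs of sums from the same donor and different sites (range 0.853 to 0.952). It was 0.875 for 39 pairs from the same site and different donors (0.754 to 0.944). The difference was 0.0379. A permutation test of donor labels within sites, counting both directions, gave p = 0.00011. These permutations leave the same-site pairs as they are. The p therefore sets the same-donor pairs against pairs from different sites with shuffled donors. Pairs of different donors and different sites had a median of 0.864. Whether the same-donor median exceeds the same-site median was not itself tested. The correlations are across genes, which are not independent replicates. Among the 2000 genes of largest variance the medians were 0.616 and 0.473. Without donor F the difference was 0.0189, with permutation p = 0.00097. Libraries of the same donor and site, in 17 pairs, correlated at 0.932 to 0.976, and no pair agreed within sampling noise.

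The first comparison asked which genes differed between liver metastases and the primary breast tumours of the same donors. The genes with the largest differences that passed the test were lower in the liver metastases. *FABP4*, the fatty acid carrier of adipocytes and some macrophages, fell by 8.96 on the log2 scale (SE 1.27, 3 of 3 donor pairs, adjusted p = 0.0244). *ADIPOQ*, which encodes the fat hormone adiponectin, had 10124 counts in breast and 0 in liver in the 3 paired donors, at least 3460-fold lower in liver. Of these counts 83.8% lay in donor E, and without that donor the bound was 421-fold. *SFRP2*, a secreted Wnt modulator of fibroblasts, fell by 9.39 ± 1.34 (SE), *PRRX1*, a mesenchymal transcription factor, by 4.85 ± 0.80 and *MMP2*, a matrix-degrading protease, by 4.30 ± 0.71, each in 3 of 3 pairs. Of 30328 genes tested, 3 were higher and 70 lower in liver metastasis at adjusted p under 0.05.

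The other named genes that were lower included *CIDEA*, a lipid droplet protein, with 2 counts in liver against 1818 in breast in the paired donors, a ratio of 931 with a counting interval of 257 to 7690. Of its breast counts 88.7% lay in donor E, without whom the ratio was 159. *TRIM63*, a ubiquitin ligase of muscle, fell by 10.69 ± 1.69 (SE), and was at −5.53 and not past the threshold without donor F. *STYXL2*, a muscle gene, had 1 count against 3244, a ratio of 3320 with an interval of 596 to 131000, but 99.4% of its breast counts lay in donor F, and without that donor it was at least 9.09-fold lower. *HOXA7*, a homeobox transcription factor of body patterning, fell by 8.27 ± 0.93, with 9 counts in all 7 liver sums and 936 in the 3 breast sums. *ADIPOQ-AS1*, which overlaps *ADIPOQ* on the opposite strand of chromosome 3, was at least 1550-fold lower (187-fold without donor E), and reads of the 2 genes cannot be told apart where counting ignored strand. The 3 genes that were higher were *CFHR2* and *SERPINA7*, each in 2 of 3 pairs, and *SHTN1*, in 3 of 3. *CFHR2*, a complement factor H-related gene expressed in liver, had 71 counts in the paired liver sums and 0 in breast, at least 23.1-fold higher, with 97.2% of the counts in donor G, without whom 2 were left, too few for a fold. It is a member of a family of near-identical genes, so its reads are uncertain. *SERPINA7*, the thyroxine-binding globulin of liver, had 30 counts against 0, at least 9.77-fold higher, with 96.7% of them in donor G, without whom there was likewise no fold. *SHTN1*, which encodes the neuronal growth protein shootin, rose by 2.19 ± 0.37 (SE, adjusted p = 0.0467).

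**Figure D1:**
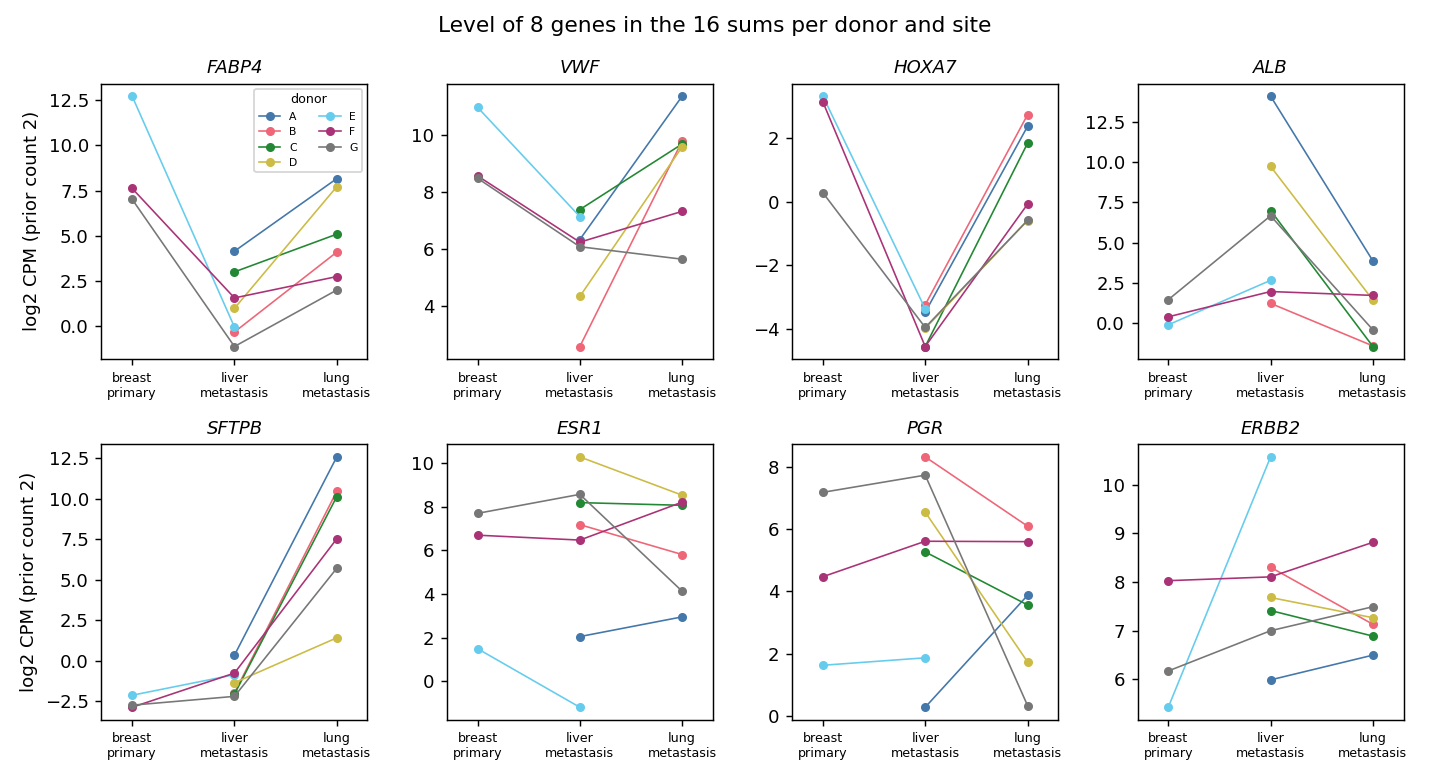
Log2 CPM (vertical axes, prior count of 2) of 8 genes in the 16 sums, by site (horizontal axes), with 1 point per donor and site and lines joining the sites of a donor. *FABP4* and *HOXA7* are lower in liver than in breast in 3 of 3 pairs, *SFTPB* is higher in lung than in liver in 6 of 6 pairs, and *ESR1*, *PGR* and *ERBB2* passed the test in 0 of 3 comparisons.

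Among the gene lists, adipocyte genes had the lowest median in liver metastasis against breast, −4.29, and 13 of 13 members were negative. Of these, 3 fell and 9 passed when adjusted over the list alone, including *CD36* (−4.47 ± 0.96) and *LPL* (−4.29 ± 0.83). The list's camera adjusted p was 1.5e-20 with the preset correlation, and its adjusted p was 0.0916 with an estimated correlation. Muscle genes had a median of −3.73, 0 of 10 passed over all genes and 5 when adjusted over the list alone (camera adjusted p = 1.13e-05, adjusted p = 0.323 with an estimated correlation). The breast sum of donor F had a mean log2 CPM of 7.73 over the muscle list, against 0.85 in donor E and 2.61 in donor G, and the median difference was −6.78 in donor F, −0.94 in donor E and −2.71 in donor G. In donor E the list's mean was higher in liver, at 1.40. Endothelial genes had a median of −2.62, with *VWF* at −3.37 ± 0.99 and *PECAM1* at −2.83 ± 0.77. Of the 14 endothelial genes, 0 passed over all genes and 12 when adjusted over the list alone (camera adjusted p = 2.42e-18, adjusted p = 0.323 with an estimated correlation). Mesenchymal transition genes had a median of −1.56, with 2 members that fell and 7 when adjusted over the list alone, among them *TWIST1* (−3.89 ± 0.77) and *VIM* (−1.83 ± 0.63). Their camera adjusted p was 3.62e-08, with an adjusted p of 0.378 with an estimated correlation. In whole tissue the mesenchymal genes cannot be assigned to tumour cells or to other cells, here and in the other comparisons. Immediate early and AP-1 genes, which respond to growth signals and to tissue handling, had a median of −1.55, and 7 of 18 passed when adjusted over the list alone, among them *EGR1* (−3.09 ± 0.57). Their camera adjusted p was 2.74e-09, with an adjusted p of 0.323 with an estimated correlation. Fibroblast and matrix genes had a median of −0.98 with *SFRP2* as the 1 member that fell, and 3 passed when adjusted over the list alone, while *COL1A1* was at 0.22 ± 0.86 (camera adjusted p = 0.00129, adjusted p = 0.467 with an estimated correlation). The list's median was lower in liver in 2 of 3 donors (−1.46 to 1.16).

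T and NK cell genes were negative in 17 of 17 members in liver metastasis against breast, with a median of −1.20 (camera adjusted p = 0.000299, adjusted p = 0.49 with an estimated correlation, and 0.959 without the donor block). Macrophage and Kupffer genes had a median of −1.32, with *FABP4* as the 1 member that fell (camera adjusted p = 4.14e-05, adjusted p = 0.467 with an estimated correlation, and 0.173 without the donor block), and the list was lower in liver in 2 of 3 donors (−2.30 to 0.96). Mitochondrially encoded genes were negative in 13 of 13 members, with a median of −1.09 (camera adjusted p = 1.84e-05, adjusted p = 0.467 with an estimated correlation, and 0.484 without the donor block). The median difference of these genes was −2.63 in donor E, −2.32 in donor F and 0.44 in donor G.

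Hepatocyte genes were on the positive side in 19 of 20 members, with a median of 3.72. None of the 20 passed over all genes, and 1 passed when adjusted over the list alone (camera adjusted p = 2.56e-06, adjusted p = 0.467 with an estimated correlation). The median difference was 4.41 in donor G, but 1.01 in donor E and 0.56 in donor F. *ALB*, which encodes serum albumin, was at 4.94 ± 1.78 (adjusted p = 0.293). Liver transcription factors had a median of 2.61, 0 of 13 passed over all genes and 1 when adjusted over the list alone (camera adjusted p = 0.00287, adjusted p = 0.467 with an estimated correlation), and the pairs themselves lay lower, at 0.18 to 1.32. Proliferation genes were positive in 22 of 22 members, with a median of 1.65, and 0 passed in either count. Their camera adjusted p was 2.18e-08, their adjusted p 0.467 with an estimated correlation, and the list's median was higher in liver in 2 of 3 donors (−0.82 to 4.69). *MKI67*, the usual marker of dividing cells, was at 2.14 ± 1.11. ER and luminal identity genes had a median of 1.27 (18 of 20 positive, camera adjusted p = 0.00023, adjusted p = 0.467 with an estimated correlation), with 1.88 in donor E, 0.44 in donor F and 0.65 in donor G. The HER2 amplicon list had a median of 1.40, and 1 of its 8 members passed when adjusted over the list alone (camera adjusted p = 0.000299, adjusted p = 0.378 with an estimated correlation). Its median difference was 3.52 in donor E, whose breast library was low in *EPCAM* (1.45 log2 CPM), 0.65 in donor F and 0.35 in donor G, and without that library the list's median was 0.77. The tumour's own marker genes did not pass the test. *ESR1*, the oestrogen receptor, was at −0.27 ± 1.06, *PGR*, the progesterone receptor, at 0.56 ± 1.32, *ERBB2* at 1.82 ± 0.77, *FOXA1* at 2.22 ± 1.15, *GATA3* at 1.03 ± 0.69 and *KRT19*, a keratin of luminal epithelium, at 1.70 ± 1.09. *SFTPC*, a lung surfactant gene, was at −1.52 ± 1.89, with 18 and 9 counts in the groups.

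Without the breast library of donor E, which held *FABP4* at 12.73 log2 CPM and the epithelial gene *EPCAM* at 1.45 against 7.11 and 7.22 in the breast sums of donors F and G, 7 genes were called, of which 4 were among the 73. Without donors A to G in turn, 63, 137, 36, 38, 6, 0 and 0 genes were called, with 2834 and 4474 genes at an unadjusted p under 0.05 where edgeR gave 0, and DESeq2's Wald test called 1671 genes on the same sums.

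The second comparison asked the same of lung metastases and primary breast tumours, in 2 paired donors. Its fitted values also draw indirectly on the sums of the other donors. Of 30328 genes, 0 were higher and 1 was lower in lung metastasis by edgeR's test. That gene was *FGF21*, a hormone expressed in liver, with 0 counts in lung and 28 in breast in the paired donors, at least 6.90-fold lower in lung. Of the breast counts 92.9% lay in donor F, without whom 2 were left, too few for a fold. Lung epithelium genes had a median of 4.20 and were positive in 18 of 19 members. Of these, 11 passed when adjusted over the list alone, among them *SCGB1A1*, the secretoglobin of club cells (9.91 ± 2.51), and *NKX2-1*, the lung lineage transcription factor (8.80 ± 2.77, though higher in 1 of 2 pairs, −0.32 and 6.52). The list's camera adjusted p was 1.02e-21, and its adjusted p was 0.162 with an estimated correlation.

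Adipocyte genes were negative in 13 of 13 members in lung metastasis against breast, with a median of −3.38. Of these, 8 passed when adjusted over the list alone, including *CD36* (−3.38 ± 1.09) and *PLIN1*, a lipid droplet coat protein (−2.30 ± 0.91). The camera adjusted p was 4.47e-21, and the adjusted p was 0.104 with an estimated correlation. Muscle genes had a median of −3.21 with 4 of 10 past the threshold when adjusted over the list alone (camera adjusted p = 1e-04, adjusted p = 0.652 with an estimated correlation), and the median difference was −5.92 in donor F and −1.06 in donor G. Immediate early and AP-1 genes and mesenchymal transition genes (median −0.88) were negative in most members and had camera adjusted p of 4.29e-05 and 0.0188, and adjusted p of 0.652 and 0.802 with an estimated correlation. The mesenchymal list had an adjusted p of 0.271 without the donor block. Proliferation genes were positive in 22 of 22 members (median 0.99, camera adjusted p = 4.29e-05, adjusted p = 0.802 with an estimated correlation). ER and luminal identity genes had a median of 0.95 and B and plasma cell genes of 0.66. Their camera adjusted p were 0.0201 and 0.0313, and their adjusted p 0.802 each with an estimated correlation. The B cell list was higher in lung in 1 of 2 donors (−1.91 to 3.15). Endothelial genes had a median of −0.92 (camera adjusted p = 0.00036, adjusted p = 0.802 with an estimated correlation). *VWF* had a fitted value of 0.09 ± 1.35 but was lower in lung in 2 of 2 pairs (−2.84 and −1.25). The list's adjusted p without the donor block was 0.0759. Oxidative phosphorylation genes had a median of −0.42 (camera adjusted p = 0.000928, adjusted p = 0.802 with an estimated correlation), lower in lung in 1 of 2 donors (−0.78 to 0.27). Mitochondrially encoded genes had a median of −0.91, the HER2 amplicon list 1.03 and hepatocyte genes −0.71. Their camera adjusted p were 4.29e-05, 0.0012 and 0.00919. With an estimated correlation they were 0.802, 0.652 and 0.802, and without the donor block 0.835, 0.572 and 0.195. The mitochondrial and hepatocyte lists were each lower in lung in 1 of 2 donors. Values of the marker genes were −0.71 ± 1.16 for *ESR1*, −1.16 ± 1.58 for *PGR*, 1.48 ± 0.73 for *ERBB2*, 1.38 ± 1.01 for *FOXA1*, 0.90 ± 0.70 for *GATA3*, 1.52 ± 1.01 for *MKI67* and 1.16 ± 1.07 for *KRT19*. *SFTPC* was at 7.00 ± 1.96 and *ALB* at −1.40 ± 1.63, and none of these 9 genes passed.

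At an unadjusted p under 0.05, 1695 of 30328 genes stood in lung against breast, little more than the share of 0.05 that no change would give. DESeq2 called 286 genes and limma-voom 4. The *FGF21* value came from 21 counts in lung and 30 in breast over all donors, and its call was lost without any of donors A to G and without the donor E breast library or the donor A liver libraries.

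No gene passed in the same direction in both metastatic sites against breast with edgeR, where independent lists of these sizes would share 0 higher and 0.00231 lower genes. DESeq2 gave 176 such genes and limma-voom gave 4. Unadjusted p under 0.05 held for 3768 genes in liver and 1695 in lung against breast. Fold changes of the sites against breast correlated at r = 0.655 across 30328 genes, where 12 simulated sets with no effect and the same breast sums gave a mean of 0.751. The covariance was 1.02 against 0.575 in the simulated sets, a difference of 0.446. Signs were the same in 73.9% of genes, against a mean of 76.6% in the simulated sets. By the correlation and the signs, the shared breast sums alone would give as much likeness as was seen, while the covariance was higher than they gave. The 3 breast sums were too few to divide, so how much of the likeness comes from the shared breast samples was not settled.

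The third comparison set liver against lung metastases in 6 donors, and the largest differences included genes known from the host organs. *CFHR2* was higher in liver by 10.18 ± 0.48 on the log2 scale (SE, 6 of 6 pairs, adjusted p = 0.000146). Donor A held 97.2% of its liver counts and all 11 of its lung counts. Without that donor it was at 8.50 (adjusted p = 0.225), and with 0 counts left in lung only a bound of 84.4-fold stood. *GC*, the vitamin D-binding protein made by hepatocytes, was higher by 9.62 ± 1.30, and *APCS*, the serum amyloid P component, by 9.31 ± 1.04. *SFTPB* and *SFTPA1*, which encode lung surfactant proteins, were lower in liver, at −9.96 ± 1.44 and −9.25 ± 1.19 (liver minus lung), in 6 of 6 pairs. Of 30328 genes, 20 were higher in liver and 39 higher in lung.

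Other genes higher in liver metastasis were *SERPINA7* (9.23 ± 0.58), the apolipoprotein gene *APOA4* (8.88 ± 1.27), *FGF21* (8.83 ± 0.77), the steroid sulfotransferase gene *SULT2A1* (8.81 ± 1.38) and *FGA*, which encodes fibrinogen alpha (5.97 ± 0.96), each in 6 of 6 pairs. Donor A held 96.2%, 98.6%, 99.5%, 90.9% and 98.1% of their liver counts in that order, and all lung counts of *SERPINA7* and *FGF21*. Without donor A these 2 genes had 0 counts in lung and were at least 38.6-fold and 12.7-fold higher in liver. *GC* and *APCS* had 86.4% and 89.1% of their liver counts in donor A. *SLC2A2*, the glucose transporter of hepatocytes, had 1918 counts in liver and 2 in lung in the paired donors, a ratio of 993 with a counting interval of 275 to 8210 (730 without donor A, who held 60.9% of the liver counts). Genes higher in lung metastasis included *SFTPC* (−8.52 ± 1.30, liver minus lung), *TBX5* (−7.62 ± 1.01), a transcription factor of heart, limb and lung mesenchyme, *HOXA7* (−6.38 ± 0.74) and *SFRP2* (−5.88 ± 0.94). *CIMIP1*, a gene of ciliary microtubules, had 3 counts in liver and 1610 in lung (lower in liver in 5 of 6 pairs), a ratio of 518 with an interval of 177 to 2510. *TBX5-AS1* (−7.70 ± 0.85) overlaps *TBX5* on the opposite strand, and *SFTPA1* has a near-identical neighbour, *SFTPA2*, so counts of these genes are uncertain. The mitochondrial tRNA genes *MT-TC* (−3.27 ± 0.48), *MT-TY* (−3.22 ± 0.48) and *MT-TN* (−3.19 ± 0.51) also fell, in 6 of 6 pairs.

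**Figure D2:**
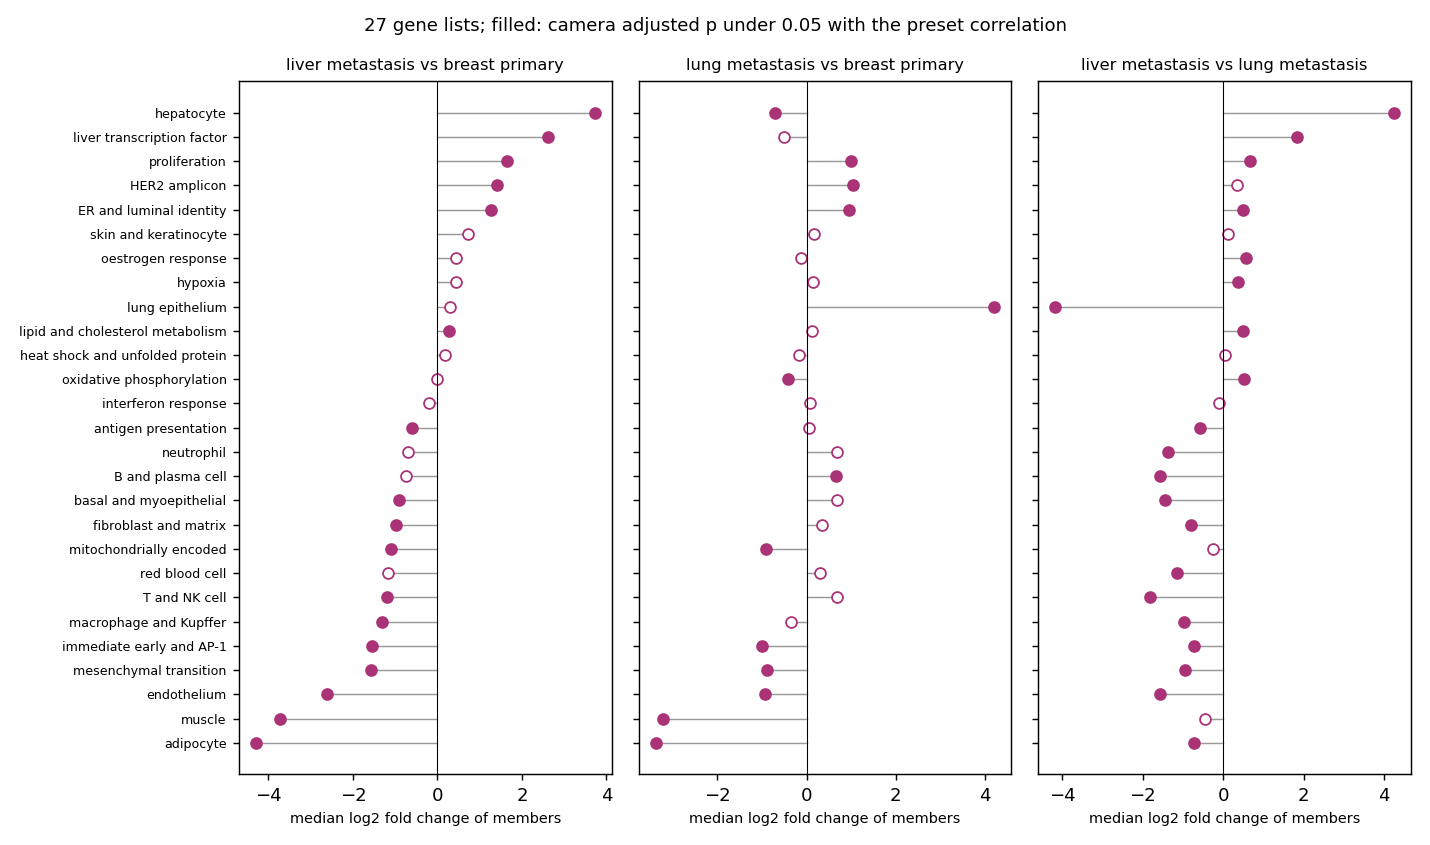
Median log2 fold change of the members (horizontal axes) of 27 gene lists (vertical axis) in the 3 comparisons, with filled points where camera's adjusted p with the preset correlation was under 0.05. Adipocyte genes have the lowest median against breast in both metastatic sites (−4.29 and −3.38), and hepatocyte (4.24) and lung epithelium genes (−4.18) stand apart between liver and lung, while 0 lists passed with an estimated correlation.

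Lung epithelium genes were negative in 19 of 19 members in liver against lung, with a median of −4.18. Of these, 3 fell and 15 passed when adjusted over the list alone, among them *SCGB1A1* (−8.54 ± 1.68) and *NKX2-1* (−8.47 ± 2.22). The camera adjusted p was 1.11e-22, and the adjusted p was 0.213 with an estimated correlation. Hepatocyte genes were positive in 20 of 20 members, with a median of 4.24. Of these, *FGA* rose and 13 passed when adjusted over the list alone (camera adjusted p = 9.27e-21, adjusted p = 0.228 with an estimated correlation), while *ALB* was at 6.34 ± 1.52 (adjusted p = 0.145). Liver transcription factors were positive in 13 of 13 members, with *HNF4A* at 4.31 ± 1.47, and 6 passed when adjusted over the list alone (camera adjusted p = 2.06e-09, adjusted p = 0.228 with an estimated correlation). The median log2 CPM difference of the hepatocyte list ran from −0.11 to 9.66 over the donors, that of the liver transcription factors from −0.35 to 5.92, each higher in liver in 5 of 6, and that of the lung epithelium list from −7.94 to −0.37, lower in 6 of 6.

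T and NK cell genes were negative in 17 of 17 members in liver against lung, with a median of −1.82 and *CD3E* at −2.16 ± 0.83. None passed over all genes and 12 when adjusted over the list alone (camera adjusted p = 3.95e-11, adjusted p = 0.286 with an estimated correlation), and the list was lower in liver in 5 of 6 donors (−4.24 to 0.88). Endothelial genes were negative in 14 of 14 members, with a median of −1.58, *VWF* at −3.46 ± 1.01 and *PECAM1* at −1.94 ± 0.65. Again 0 passed over all genes and 12 when adjusted over the list alone (camera adjusted p = 5.06e-12, adjusted p = 0.286 with an estimated correlation), and the list was lower in 5 of 6 donors (−4.44 to 0.27). B and plasma cell genes had a median of −1.56, neutrophil genes −1.37, macrophage and Kupffer genes −0.97, antigen presentation genes −0.58 and red blood cell genes −1.14. Their camera adjusted p were 0.000219, 0.000249, 0.000171, 0.000147 and 0.00551, and their adjusted p were 0.359, 0.368, 0.418, 0.368 and 0.418 with an estimated correlation. The B cell list was lower in liver in 6 of 6 donors (−3.55 to −0.18), the neutrophil list in 4 (−2.37 to 0.58), the macrophage list in 3 (−5.47 to 0.78), the antigen presentation list in 5 (−2.05 to 0.04) and the red blood cell list in 4 (−3.60 to 1.34). The red blood cell list had an adjusted p of 0.749 without the donor block. Basal and myoepithelial genes had a median of −1.44, with *KRT14* at −5.29 ± 1.61 (camera adjusted p = 9.01e-05, adjusted p = 0.286 with an estimated correlation). Mesenchymal transition genes had a median of −0.95, fibroblast and matrix genes −0.79, immediate early and AP-1 genes −0.72 and proliferation genes 0.67. Their camera adjusted p were 1.73e-05, 0.000121, 0.00121 and 0.000321, and with an estimated correlation 0.359, 0.359, 0.413 and 0.501. The first 3 lists were each lower in liver in 5 of 6 donors, and the proliferation list was higher in 4 of 6. Oxidative phosphorylation genes were positive in 17 of 17 members, with a median of 0.53 (camera adjusted p = 1.73e-05, adjusted p = 0.359 with an estimated correlation). The list was higher in liver in 6 of 6 donors (0.008 to 1.45). Its mean in the liver sum of donor A stood apart, at 7.87 log2 CPM with the nearest donor at 6.77.

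Oestrogen response genes had a median of 0.57 in liver against lung (camera adjusted p = 0.000182, adjusted p = 0.286 with an estimated correlation), and lipid and cholesterol genes 0.48 (camera adjusted p = 0.00189, adjusted p = 0.286 with an estimated correlation). The lists were higher in liver in 5 of 6 (−0.41 to 1.98) and 4 of 6 donors (−0.22 to 1.21). ER and luminal identity genes had a median of 0.49 and adipocyte genes of −0.73. Their camera adjusted p were 0.0117 and 0.0304, with 0.42 and 0.501 with an estimated correlation, and 0.0723 and 0.234 without the donor block. The luminal list was higher in liver in 3 of 6 donors, and the adipocyte list lower in 4 of 6. Hypoxia genes had a median of 0.37 (camera adjusted p = 0.00564, adjusted p = 0.472 with an estimated correlation). Their median difference was 2.77 in donor A and −0.80 to 0.36 in donors B, C, D, F and G, and the list's median was 0.021 without the liver libraries of donor A. Mitochondrially encoded genes (−0.25), interferon response genes (−0.11), heat shock and unfolded protein genes (0.05) and skin and keratinocyte genes (0.13) had camera adjusted p of 0.149, 0.563, 0.247 and 0.427. *ESR1* (0.43 ± 0.77), *PGR* (1.72 ± 1.20), *ERBB2* (0.34 ± 0.53), *FOXA1* (0.84 ± 0.79), *GATA3* (0.13 ± 0.54), *MKI67* (0.62 ± 0.74) and *KRT19* (0.54 ± 0.80) did not pass. The liver libraries of donor A held *ALB* at 14.11 log2 CPM against 1.22 to 9.74 in the other 6 donors. Their *EPCAM* was at 3.73, against 7.27 to 7.95 in the others. Without the liver libraries of donor A the count was 0 with edgeR, and the hepatocyte list's median was 3.37. An unadjusted p under 0.05 then held for 3428 genes, against 3874 with these libraries. Without donor B, C, D, F or G, each of which also had both sites, 19 to 53 calls remained. The loss of 1 pair thus does not by itself account for the 0. What else took the calls was not tested. Without donors A to G in turn the count was 0, 39, 25, 53, 49, 50 and 19, without the donor block it was 18, and DESeq2's Wald test called 1933 genes.

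The authors' deposited tables compared tumours of each organ with normal tissue of that organ. The normal columns came from outside this series, so in these calls tumour cannot be told apart from the source of the data. The 6, 14 and 12 tumour libraries of breast, liver and lung came from 3, 7 and 6 donors. Whether the authors allowed for shared donors is not given in the sources used here. The authors' deposited table for breast listed 5650 of 48707 rows as higher and 14447 as lower in tumour at adjusted p under 0.05. That for liver listed 8435 and 10520 of 48515, and that for lung 5714 and 17197 of 49925. Their logFC columns lay between −2.38 and 3.34 on a scale the tables do not give, so they are printed as deposited values and not as folds. In the authors' deposited liver table, 20 of 20 hepatocyte genes and 13 of 13 liver transcription factors were lower in metastasis than in normal liver, and 20 of 22 proliferation genes and 11 of 16 fibroblast and matrix genes were higher. *ALB* had a deposited logFC of −2.06, *KRT19* of 1.97, *GATA3* of 1.84, *PGR* of 1.59 and *MKI67* of 1.11 in the authors' deposited liver table, all past the threshold, while *ESR1* (0.74) was not. The authors' deposited lung table listed 16 of 19 lung epithelium genes, 17 of 18 macrophage genes, 16 of 16 antigen presentation genes and 16 of 17 T and NK cell genes as lower. Lists of other kinds were lower too, such as oxidative phosphorylation (16 of 17) and immediate early and AP-1 genes (17 of 18). These counts thus do not single out immune genes. ER and luminal identity genes were higher in 10 of 20 and lower in 1. *GATA3* (1.73), *FOXA1* (1.33) and *ESR1* (1.32) were higher than in normal lung. The authors' deposited breast table listed 13 of 13 adipocyte, 13 of 14 endothelial and 14 of 18 immediate early and AP-1 genes as lower, and *ESR1* (0.00), *PGR* (−0.21) and *ERBB2* (−0.27) as not past the threshold. Antigen presentation (15 of 16) and oxidative phosphorylation genes (15 of 17) were lower there too, while 5 of 11 muscle genes were higher and 1 lower.

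Large positive logFC in the authors' deposited tables often belonged to genes whose mean in normal tissue, computed from the deposited AveExpr and logFC, was 0. Among the highest were *MRPL53*, a mitochondrial ribosomal protein gene (3.34 in the authors' deposited breast table and 2.23 in that for liver), and *DERPC* (2.64 in that for lung), each with a normal mean of 0. Among the highest with a normal mean above the tolerance of 1e-06 were *CXCR5*, a chemokine receptor of B cells, at 3.30 in the authors' deposited breast table, *FSCN3* at 2.20 in that for liver and *SPATA21* at 2.62 in that for lung. The normal means of these genes may still lie close to 0. Beside them stood *MIR6721* (3.33 in that for breast and 2.61 in that for lung) and *MED4-AS1* (3.30 in that for breast and 2.21 in that for liver). The lowest included *FLG2* (−2.13) and *LORICRIN* (−2.11), genes of the skin barrier, in the authors' deposited breast table. In the authors' deposited liver table they included the liver genes *ABCC2* (−2.13), *AFM* (−2.12) and *MAT1A* (−2.12), and in that for lung *CRNN* (−2.28), a gene of squamous epithelium, and *SMYD1* (−2.26), a gene of muscle.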

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

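The tests of the donor E breast library on the number of lower calls, the splits of the breast comparisons and the tests on the deposited tables were chosen only after the result was seen. The limit to splits that part as many pairs, the comparison with leaving out donors F and G, and the setting apart of groups with ties, were also set after it. The values of donor E breast and donor A liver had been looked at before the other tests were written. In 128 groups of sums, 23 had a highest or lowest donor far from the rest by the gap of that donor to its nearest neighbour, set against the whole range of the group. Chance gives about 1 in 20 groups, here 6.4, but that rate does not hold where donors are tied at 0 counts, since a few counts in another donor then stand apart by themselves. In 22 groups 2 or more donors had 0 counts, and 10 of the 23 were among them. In the other 106 groups 13 stood apart, where chance gives 5.3, and as the groups share donors and genes, this excess was not tested. Of the 23, 10 were the liver sum of donor A.

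In liver metastasis, donor A stood apart with *FGF21* at 8.42 log2 CPM (nearest donor −0.86), *FGA* at 15.40 (7.31) and *KRT19* at 4.54 (8.87). List means of the same sum were 8.21 for red blood cell genes (nearest 1.54), 7.21 for macrophage and Kupffer genes (3.84), 7.87 for oxidative phosphorylation genes (6.77), 2.58 for adipocyte genes (0.51) and −1.52 for muscle genes (0.21). Near the floor, *STYXL2* was at −2.88 and *CIDEA* at −2.45 in donor A liver, *ADIPOQ* at −4.02 in donor C and *CIMIP1* at −3.25 in donor B. *MMP2* was at 8.57 in donor C liver (nearest 6.21), and skin and keratinocyte genes had a mean of 1.19 in donor E liver (nearest −1.29).

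In lung metastasis, donor A stood apart with the liver genes *APCS* at 0.54 log2 CPM, *APOA4* at 0.49, *FGF21* at −0.73, *CFHR2* at −1.58, *SULT2A1* at −1.58 and *SERPINA7* at −2.31, all higher than in the other 5 donors. *SHTN1* was at 6.40 in donor G (nearest 5.19), the HER2 amplicon list had a mean of 5.83 in donor F (nearest 4.59), and T and NK cell genes had a mean of −0.68 in donor F (nearest 2.42).

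For 9 named genes called in a comparison with breast, the changes from breast in the 2 metastatic sites also differed, but in this model that difference is the liver against lung comparison already given. The breast sums cancel in it, so it is no further test of a change from breast, and with edgeR 0 of the 59 calls were left without the liver libraries of donor A (3428 genes at unadjusted p under 0.05). The difference, liver minus lung, was 10.18 for *CFHR2*, 9.23 for *SERPINA7*, 8.83 for *FGF21*, −7.70 for *TBX5-AS1*, −6.38 for *HOXA7*, −5.88 for *SFRP2*, −3.27 for *MT-TC*, −3.22 for *MT-TY* and −3.19 for *MT-TN*, in 6 of 6 pairs each. The adjusted p lay between 0.000146 for *CFHR2* and 0.0407 for *SFRP2* and *MT-TN*.

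Fat genes and the number of lower calls in liver metastasis against breast were weighed against the breast library of donor E, with *FABP4* at 12.73 log2 CPM and *EPCAM* at 1.45. Without it the adipocyte list had a median of −3.53, so the library did not make that difference alone, while 4.29% of the 70 lower calls remained. Without donor F or donor G 0% remained (edgeR, with 2834 and 4474 genes at unadjusted p under 0.05), so the loss of calls does not single out donor E, and whether its library decides the count cannot be told apart from the loss of any breast donor. A difference between primary and metastatic tumour cells stays open and untested.

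Hepatocyte genes, with a median of 4.24 in liver against lung metastasis (adjusted p = 0.228 with an estimated correlation), were weighed against hepatocytes within the tissue. Over the 7 liver sums the other 19 hepatocyte genes followed *ALB* with a median r of 0.964 (highest 0.987). The mean of those genes correlated with *ALB* at r = 0.979 (exact permutation p = 0.00198) and rho = 0.857 (exact permutation p = 0.0238), and at 0.986 without the 2 donors farthest from the median. Without donor A liver the list's median was 3.37, so that donor alone did not make the difference, though all 59 calls were lost with edgeR (3428 genes at unadjusted p under 0.05, and DESeq2, with 1933 calls on all sums, was not run without it). Hepatocytes in the tissue may account for the pattern, and liver genes switched on in tumour cells stay open, since they would rise together too.

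The other splits of the sums differ from the real one in how many donor pairs they part, so the real one was compared with those that part as many. Between the metastatic sites, 1 of 33 such splits, the real one, gave as many calls as the 59 seen, a share under 0.05. The highest other gave 2. No smaller share is possible with 33 splits. Splits that exchange the sites of some donors also count the site difference as spread, which lowers their calls. The real split thus gave the most calls, but chance is not excluded for that count. Over all 72 splits the number as large was 1. In liver against breast 4 splits parted as many pairs, too few for a share under 0.05, with 73 calls in the real one and at most 0 in the others. Over all 41 splits the number as large was 1, and the highest other gave 1. In lung against breast 8 splits parted as many pairs, again too few, with 1 call in the real one and at most 1 in the others. Over all 41 splits the number as large was 4.

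The largest positive values in the authors' deposited tables belonged to genes with a normal mean of 0 in 41, 26 and 41 of the top 50 of the breast, liver and lung tables. Of the IDs listed more than once, 119 over the 3 tables (38, 41 and 40 in those for breast, liver and lung), 108 had 1 entry at 0 and 1 above, 36 in each table. The same ID can be counted in more than 1 table. In the authors' deposited breast table the upper entry had a median logFC of 3.01 and the lower one of −0.56. A join to an empty second entry of the normal table may account for these IDs, the bounds of this test having been set after the value was seen. Genes left uncounted in normal tissue of every organ were not decided, as 33.2% of 2178 higher IDs with a normal mean of 0 had it in all 3 organs, against 25.8% if the organs were independent. Genes without a name in the normal table were not the cause, since 0 of 3800 such genes were listed in a deposited table.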

How the results depend on the processing

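Fits without the breast library of donor E or the liver libraries of donor A were chosen only after the result was seen. In the order liver against breast, lung against breast and liver against lung, edgeR called 73, 1 and 59 genes. DESeq2's Wald test called 1671, 286 and 1933, limma-voom 226, 4 and 538, no filter 490, 14 and 414, and single libraries 5139, 1716 and 5467. The first library of each donor and site gave 38, 0 and 27, donors with all 3 sites 0, 0 and 0, and the compared sites alone 0, 0 and 1. Without the donor block the counts were 104, 0 and 18, of which 23, 0 and 10 were shared with the blocked calls. Without the breast library of donor E they were 7, 0 and 48, without the liver libraries of donor A 64, 0 and 0, and without both 1, 0 and 0. Leaving out each donor gave 0 to 137, 0 to 1 and 0 to 53, and the 1 gene in lung against breast without donor D was another gene. Where edgeR gave 0, between 1272 and 4474 genes had an unadjusted p under 0.05, of which the lowest is no more than the share of 0.05 that no change would give. Genes called in both sites against breast were 0 by edgeR, 176 by DESeq2, 4 by limma-voom, 10 with no filter and 1098 with single libraries. Lists past the threshold, 17, 13 and 21, were 0, 0 and 0 with an estimated correlation. The fit of single libraries takes libraries of the same donor and site as separate replicates of the site. Its counts are therefore inflated and are no evidence of more changed genes. Fewer samples lower the power of the reduced fits, and for the other settings the cause was not tested.

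Of 644 values of 34 called gene results, 336 kept the direction and the call, 308 kept the direction and lost the call and 0 turned. Of 519 values of 26 results not past the threshold, 485 stayed, 8 passed and 26 turned, for which the cause was not tested.
*ESR1* in liver against breast was at 1.55 without the donor block, 0.093 with single libraries, 0.56 in donors with all 3 sites, 0.64 without the breast library of donor E and 0.72 without both, and lay between −1.15 and 0.64 with 1 donor left out. In lung against breast it was at 0.69 without the block, 0.028 in donors with all 3 sites and 0.050 without the donor E library (−2.43 to 0.050 with 1 donor left out), and in liver against lung −0.16 to 1.29 with 1 donor left out. *SFTPC* in liver against breast was at 0.11 without the block, 2.59 with first libraries and 0.20 in donors with all 3 sites. *ALB* in lung against breast was at 1.16 without the block and 0.47 in donors with all 3 sites. In those donors *MKI67* was at −0.020 in liver against breast, and in liver against lung *ERBB2* was at −0.61, *FOXA1* at −0.97, *GATA3* at −0.62 and *MKI67* at −1.15. *GATA3* in liver against lung was at −0.0044 with first libraries, and −0.29 to 0.62 with 1 donor left out. *PGR* lay between −0.10 and 1.10 in liver against breast and between −2.95 and 0.031 in lung against breast with 1 donor left out. The similarity by donor kept its direction, with differences of 0.0189 to 0.143. Of the calls of the authors' deposited tables, 15074, 12810 and 15329 had also an absolute logFC over 1, and 18687, 17713 and 21776 were left without genes of normal mean 0.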

Other observations

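The groups of genes in the paragraphs that follow, and their tests, were chosen only after the calls were seen. Some single genes called by edgeR's test belonged to no fixed list, and no enrichment of their kind was tested. In liver metastasis against breast *ACKR1*, a chemokine-binding receptor, fell by 7.41 ± 0.91 on the log2 scale (SE, adjusted p = 0.0162), *SELP*, a selectin, was at −5.51 ± 0.89 (0.0394) and *SELE* at −3.82 ± 0.50 (0.0223), in 3 of 3 pairs each. *ACKR1* (−5.11 ± 0.64) and *SELE* (−2.41 ± 0.36) were also lower in liver than in lung metastasis, in 6 of 6 pairs. Single genes higher in lung than in liver metastasis, in 6 of 6 pairs each, were *DAW1* (−5.45 ± 0.89), *TEKT1* (−5.12 ± 0.82), *DRC1* (−5.05 ± 0.67), *HOATZ* (−4.92 ± 0.78) and *CFAP77* (−4.68 ± 0.69).

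Mitochondrial tRNA genes were negative in 22 of 22 members in liver metastasis against breast, with a median of −2.10, and of −0.72 without the donor block, where 2 were positive and 0 fell by edgeR. With the block, 4 fell. As these 4 had prompted the choice, the family was tested without them, and the other 18 had a median of −2.07 and an adjusted p of 0.167 with an estimated correlation, over 6 family tests. The 4 that fell, *MT-TA* (−4.57), *MT-TN* (−4.63), *MT-TC* (−4.51) and *MT-TY* (−4.15), lie next to each other on 1 strand of the mitochondrial genome. The median difference was −3.23, −2.97 and −1.08 in donors E, F and G, beside −2.63, −2.32 and 0.44 for mitochondrially encoded genes. Mitochondrial counts took 1.74 to 2.16% of the liver and 5.89% of the breast libraries of donor E, 1.25 to 1.29% and 3.48 to 6.36% in donor F, and 5.52 to 14.5% and 7.25 to 10.4% in donor G. Without the breast library of donor E the median in liver against breast was −1.49 with 0 calls by edgeR. In lung against breast the median was −1.15 (adjusted p = 0.188 with an estimated correlation, over the same 18) and turned to 0.28 without the donor block, and in liver against lung it was −0.86 (adjusted p = 0.292 with an estimated correlation, over the same 18) and −0.67 without the block. HOX genes had medians of −1.51, −0.60 and −0.34 in liver against breast, lung against breast and liver against lung, and of −0.69, −0.63 and 0.21 without the donor block, where the last turned. Without *HOXA7*, which had prompted this family, their adjusted p were 0.292, 0.332 and 0.586 with an estimated correlation.

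Receptor genes had unlike levels between sites within some donors, given here beside epithelial genes and untested. In donor G, *ESR1* was at 4.12 log2 CPM and *PGR* at 0.34 in lung metastasis, against 7.69 and 7.17 in breast and 8.56 and 7.72 in liver, while *EPCAM* was at 7.24, 7.22 and 7.27 in lung, breast and liver. In donor E, *ERBB2* was at 10.57 in liver metastasis and 5.42 in breast. The epithelial genes *EPCAM* (7.27 and 1.45) and *KRT19* (10.15 and 3.57) differed by more, and the adipocyte list had means of 0.31 and 8.54. *ESR1* in donor E went the other way, at −1.186 in liver and 1.496 in breast. *ERBB2* in the liver sums of the other donors lay lower, between 5.985 (donor A) and 8.301 (donor B). *EPCAM* in the liver sums of donors B, C, D, F and G was at 7.267 to 7.949, similar to donor E. The *ERBB2* difference between the sites of donor E therefore cannot be told apart from the epithelial content of its breast library, while *ESR1* did not follow the epithelial genes. The cause of these receptor levels was not tested.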
